A study of Mus musculus with 8 samples.

How the data were processed

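Gene expression was measured with 1-colour Affymetrix whole-transcript arrays in 8 RNA samples of mouse melanocytes, 2 each of WT sham, WT UVA, KO sham and KO UVA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells from pups were grown for 22 days in melanocyte medium, treated with 20 J/cm² UVA-1 or sham treated, and lysed 6 h later, and total RNA was amplified and labelled with biotin using the manufacturer's whole-transcript kit. The samples carry the sex label female.

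The deposited values are 1 intensity per probe set and array. Per the submitters' processing notes they were made by robust multi-array averaging (RMA: background correction, quantile normalization and summarisation of probes) in Affymetrix Expression Console 1.3.1.187. The genome build and annotation version are not given in the sources used here, and no genome was used, so no positions are given. The deposited intensity values turned out to be whole numbers from 7 to 22585 on a linear scale. The tests had been planned for log2 values, so log2 was taken here before any test; no pseudocount was needed. Rounding to whole numbers coarsens the values of dim probe sets, and 10 genes had no variance within any group.

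Of the 41345 probe sets, 23521 had a single gene symbol in the platform annotation, 1814 had several and 16010 had none in the table used. Probe sets with a single symbol were kept. For the 1082 genes with more than 1 such probe set, the one with the highest mean over the 8 arrays was used. This gave 22180 genes, of which 21994 were found by their Entrez identifier in the RefSeq gene table, with the same symbol. No dim genes were removed in the main setting. Because RMA forces near-equal distributions on the arrays, a change that moved most transcripts in 1 direction would not be seen.

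Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 4 groups over all 8 arrays, so that the groups shared a variance estimate, and 7 comparisons were made: KO against WT after sham, after UVA and averaged over both; UVA against sham in WT, in KO and averaged over both; and the interaction. Variances were moderated with eBayes with a trend on the mean level, and p-values were adjusted over all genes by Benjamini-Hochberg, with a threshold of 0.05. Adjusted p-values of single genes are from limma throughout, and all tests were two-sided. With 2 arrays per group 4 residual degrees of freedom remain. All SEs and adjusted p-values of single genes printed with a block come from the blocked fits.

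Whether the replicate numbers pair the arrays was checked before the calls of the fits were compared. Deviations from the group means correlated at 0.80 to 0.92 between all 6 pairs of groups, and the first principal component separated the numbers, so the numbers were taken to pair the arrays. The pairing comes from the data and from the shared numbers in the titles. The labels do not say what a number stands for, and there are only 2 of them. The replicate number was therefore also fitted as a block in every comparison (3 residual degrees of freedom; the averaged genotype comparison then called 7 genes). After the data were seen, each combination of genotype and number was fitted as a block for the UVA comparisons and the interaction (2 residual degrees of freedom), the arrays of each number were fitted alone, and the sham and UVA arrays of each culture were averaged. In the blocked genotype comparison the sham and UVA arrays of a culture enter as separate arrays, although they correlate at r = 0.996 to 0.997; p-values there are too small if the culture is the true unit. A genotype comparison within 1 number has a single culture per genotype, so its p-values do not test the genotype, and lists were tested there at the preset correlation only.

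Before the data were examined, 15 gene lists were fixed from general knowledge: SASP factors, CDK inhibitors, proliferation, NRF2 targets, autophagy machinery, lysosome, melanocyte pigmentation, p53 targets, ATF4 and ER stress, heat shock, immediate early genes, interferon response, lipid mediators and lipid peroxidation, cholesterol synthesis and extracellular matrix. A further 7 lists held markers of fibroblast, keratinocyte, myeloid cell, mast cell, endothelial cell, Schwann cell and skeletal muscle, cell types that a culture from pup skin could hold. Of their 525 members 474 were measured. Lists share some genes, and melanocytes express part of the matrix, SASP and Schwann cell markers. Lists were tested with camera with a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with the correlation estimated from the residuals. That estimate rests on 4 residual degrees of freedom without a block and 3 or 2 with one, so it is imprecise. The residuals without a block also hold the difference between the numbers. A call lost with an estimated correlation therefore does not show that the list was unchanged. Without a block, the lists that held with an estimated correlation were NRF2 targets in the averaged genotype comparison (0.0427), NRF2 targets (0.0287) and heat shock (0.0304) in the averaged UVA comparison, NRF2 targets in WT (0.0437), and NRF2 targets and heat shock in KO (0.0477 each). With the replicate number as a block, NRF2 targets and heat shock held in the averaged UVA comparison (0.0464 each). Per list, members past the threshold were counted over all genes and adjusted over the list alone.

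The genes named were chosen by a rule fixed beforehand: in each comparison, up to 10 genes per direction with the largest log2 fold change among those with an adjusted p under 0.05 whose arrays did not overlap between the sides, filled by the smallest p where fewer passed; Atg7 and Sqstm1; from each list the 4 members with the smallest p and members of a described count; and Xist and Y-linked genes for a sex check. The fit without a block called no gene, so the rule was applied within the blocked fits, a choice made after seeing this. Genes called with overlapping arrays were filled in by p. Ptgs2, Ptges, Plin2, Cdkn2b and further members of lists on secretion and lipid mediators are given because they bear on the study's question, whatever their p.

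The averaged comparisons were tested on simulated data before use, with 200 of the 22180 genes changed in 10 simulations. The changed genes were drawn only from those with a mean above the median of all values. The shares recovered therefore do not cover dimmer genes, which were kept in the real tests. This covered gene calls and list calls at the preset correlation, and the other statistics were not simulated. The simulated noise was independent between arrays and between genes, with no culture effect. The rates below therefore do not cover variation shared within a culture or between the genes of a list. In the averaged genotype comparison genes changed by 1 log2 unit were recovered in 47.8% of cases without a block and 87.4% with the replicate number as a block, and genes changed by 2 log2 units in 79.6% and 97.7%. In the averaged UVA comparison the shares were 45.3% without a block and 78.6% with the culture as a block for 1 log2 unit, and 80.3% and 96.1% for 2. The mean number of false calls was 6.6 for the blocked genotype fit and 5.2 for the UVA fit with the culture as a block. These arose with 200 genes changed, so they cannot be set directly against the real counts. A list shifted by 0.3 was called in 100% of simulations.

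Alternatives planned before the data were examined were a variance prior without a trend, a robust prior, leaving out the dimmest genes by mean (0.333 of all), the mean of a gene's probe sets, all probe sets, a second quantile normalization, centring on array medians, array weights, the replicate block, only the arrays of the groups compared, and leaving out each array in turn. Intervals of list medians are 95% bootstrap intervals over 10000 resamples of genes, which treat genes as independent. Plots were drawn with matplotlib 3.10.9.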

Results

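Gene expression was measured with Affymetrix whole-transcript arrays in melanocytes, the pigment cells of the skin, isolated from mouse pups 1 to 5 days old and cultured for 22 days. Cells with floxed Atg7 alleles and an active autophagy pathway (WT) were compared with cells of the same floxed genotype that also carried the Cre recombinase under the tyrosinase promoter, which deletes Atg7 in pigment cells and leaves them autophagy deficient (KO). Atg7 encodes the E1-like enzyme needed to conjugate LC3 proteins to lipid during autophagy. Cells of each genotype received either 20 J/cm² UVA-1, the long-wave part of ultraviolet A, or a sham treatment, and RNA was taken 6 h later. The 8 arrays formed 4 groups of 2, described by the submitters as biological duplicates: WT sham, WT UVA, KO sham and KO UVA. The labels number the duplicates 1 and 2 in every group. The series title raises the question whether autophagy deficient melanocytes take on a senescence associated secretory phenotype (SASP), the release of cytokines, chemokines and proteases by senescent cells, together with oxidized lipid mediators. After assignment of probe sets to single gene symbols, 22180 genes were tested. The array medians were 110 to 115 on the linear intensity scale, and the number of arrays limits the precision of every value.

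The probe set for Atg7 read 9.85 ± 0.14 in WT sham, 9.84 ± 0.19 in WT UVA, 9.46 ± 0.34 in KO sham and 9.44 ± 0.30 in KO UVA (log2, mean ± SD, n = 2 each). All 4 KO arrays lay below all 4 WT arrays, but barely: KO sham of number 1 read 9.699 and WT UVA of number 2 read 9.700. The averaged difference was -0.39 on the log2 scale, or 0.763 of the WT level. The difference did not pass the test over all genes (limma adjusted p = 1 without a block and 0.297 with the replicate number as a block), and passed when adjusted over the autophagy list alone with that block (adjusted p = 0.0342). The table used here does not say which exons the probes cover, so a probe set that lies partly or wholly outside the deleted exon cannot check the deletion. Sqstm1, which encodes the autophagy receptor p62, was 0.13 log2 units higher in KO, with an adjusted p of 0.477 with the replicate number as a block.

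The arrays grouped first by replicate number. Arrays of 1 genotype and 1 number, sham and UVA, correlated at r = 0.996 to 0.997 across genes, and arrays of the same number but the other genotype at r = 0.989 to 0.997. Duplicates of a group correlated only at r = 0.962 to 0.978. The first principal component held 77.7% of the variance and separated number 1 from number 2. The deviations of the arrays from their group means correlated between all 6 pairs of groups, at r = 0.80 to 0.92. Values with the replicate number as a block are therefore given beside the fit without it wherever they change a call. For the UVA comparisons, a fit with each combination of genotype and number as a block (called a culture here, although the labels do not say that its sham and UVA arrays came from one culture) is given as well; it was chosen after the data were seen.

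The comparison of KO with WT, averaged over sham and UVA, asks what loss of Atg7 does to the transcriptome. NRF2 targets, genes of the antioxidant response, were higher in KO as a list (adjusted p = 2.64e-09 without a block; 0.0427 with an estimated correlation, and 0.0708 with that and the replicate number as a block). SASP factors were higher as a list (5.77e-04), a call lost with an estimated correlation (adjusted p = 0.588), and of its members Mmp13 passed over all genes. Nqo1, the quinone reductase that is a standard NRF2 target, was 2.20-fold higher (log2 difference 1.13, SE 0.09). Mmp13, a collagenase, was 2.05-fold higher. With the replicate number as a block, 7 genes passed, 6 of them higher and 1 lower in KO. Ap1s2, a subunit of the adaptor complex of clathrin-coated vesicles, was higher by 1.13 log2 units (SE 0.06, adjusted p = 0.00891). Nrxn2, which encodes the synaptic adhesion protein neurexin 2, was higher by 1.32 (SE 0.09, adjusted p = 0.0142). Cyp1b1, a cytochrome P450, was higher by 1.48 (SE 0.10, adjusted p = 0.0148). Adh7, an alcohol dehydrogenase that oxidizes retinol, was higher by 1.49 (SE 0.12, adjusted p = 0.0189). Nqo1 (adjusted p = 0.0189) and Mmp13 (adjusted p = 0.0366) also passed. Moxd1, a monooxygenase related to dopamine beta-hydroxylase, fell by 0.90 (SE 0.07, adjusted p = 0.0189). All 7 differed in the same direction in both replicate numbers, which selection by the blocked fit favours, so this is not separate support. For Ap1s2, Nrxn2 and Moxd1 all 4 KO arrays also lay clear of all 4 WT arrays, while for Cyp1b1, Adh7, Nqo1 and Mmp13 the arrays of the genotypes overlapped across numbers. Ccl5 and Cxcl10, chemokines that attract T cells, were 2.31-fold and 3.07-fold higher without passing over all genes (adjusted p = 0.0780 and 0.135). The angiotensin receptor gene Agtr2 (0.97 log2 units, adjusted p = 0.0586) and Csmd1 (1.05) did not pass either. Among genes lower in KO that did not pass were Rad51ap1, a factor of homologous recombination (-0.69, adjusted p = 0.102), Nrip3 (-0.79) and Tmem108 (-0.82). Without the block limma called 0 genes, with 517 at an unadjusted p under 0.05 against 1109 expected by chance. The difference between the numbers counts as noise in that fit, which can lower the count. The limma fit with the replicate number as a block had 1970 such genes. It treats the sham and UVA arrays of a culture as separate. The sham and UVA arrays of each culture were also averaged before the fit, a setting tried after seeing the data. Then 0 genes passed without the block (257 at an unadjusted p under 0.05) and 0 with it (736). These limma fits had 2 and 1 residual degrees of freedom, which limits their power. Leaving out any single array from the blocked fit also left 0.

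**Figure D1:**
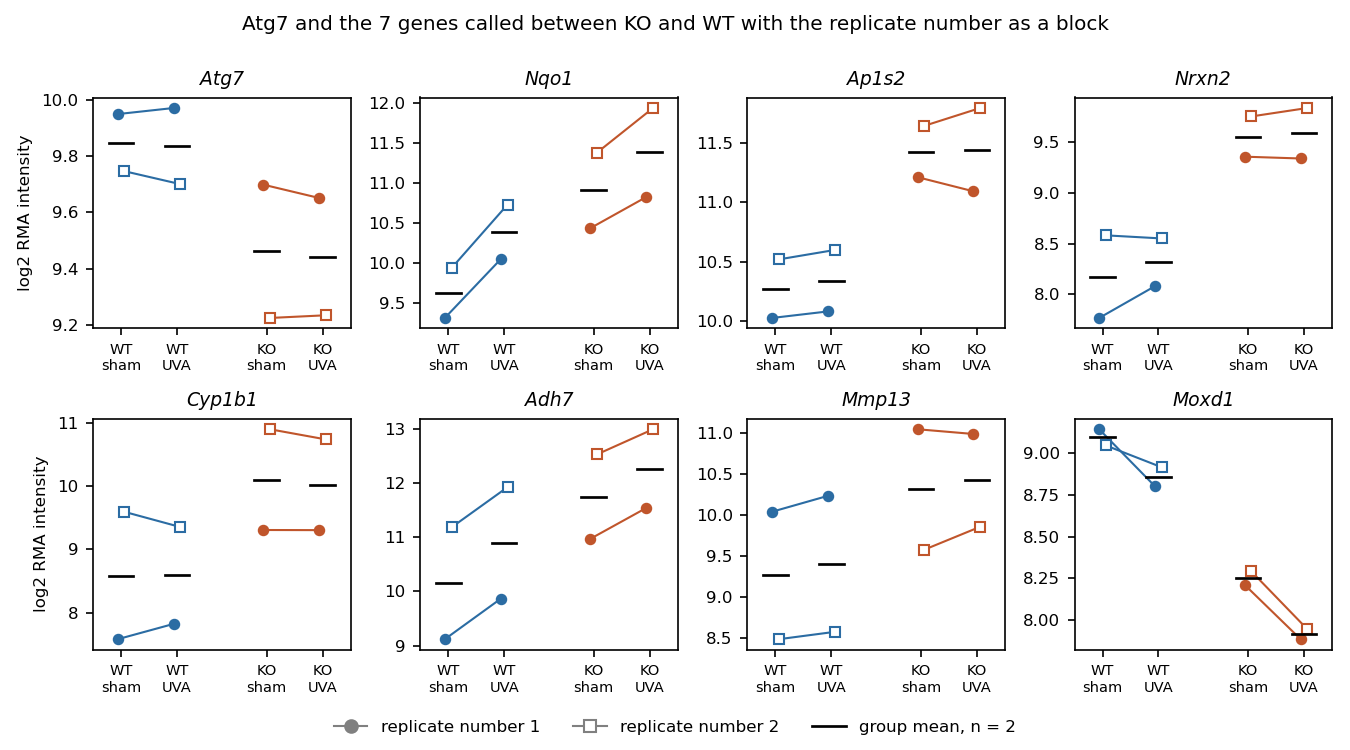
Log2 RMA intensity of Atg7 and of the 7 genes called between KO and WT with the replicate number as a block, in the 8 arrays (WT in blue, KO in orange, lines joining sham and UVA arrays of 1 genotype and number, black bars group means of 2). Atg7 read 9.85 in WT sham and 9.46 in KO sham, and the KO minus WT difference of each of the 7 genes has the same sign in number 1 and in number 2. The fit that selected these genes favours such agreement.

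Of 27 measured NRF2 targets, the genes for glutathione synthesis, quinone reduction and the pentose phosphate pathway, 25 had a positive KO minus WT difference, with a median of 0.23 log2 units. The list stood above other genes with limma's camera test (adjusted p = 2.64e-09 without a block), and this call held with an estimated correlation (adjusted p = 0.0427). The blocked values were 1.36e-17 and, with an estimated correlation, 0.0708. In the blocked fit 1 member passed over all genes and 11 passed when adjusted over the list alone, among them Gclm, a subunit of the enzyme that starts glutathione synthesis (0.27), Ephx1, an epoxide hydrolase (0.28), Taldo1 (0.29) and Aox1 (0.34). The median of the list was 0.16 in number 1 and 0.24 in number 2. Each number holds 1 culture per genotype, so values within a number are given without a test.

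Of 53 measured SASP factors, 44 had a positive difference (median 0.21, adjusted p = 5.77e-04; adjusted p = 0.588 with an estimated correlation). The blocked fit gave an adjusted p of 1.96e-11, and 0.252 with an estimated correlation. There 1 member passed over all genes and 5 passed when adjusted over the list alone: Mmp13, Ccl5, Cxcl10, the neutrophil chemokine Cxcl2 (0.85) and the stromelysin Mmp10 (0.67). The median of the list was 0.03 in number 1 and 0.31 in number 2. Markers of fibroblasts, a cell type that can grow in cultures from pup skin, moved with the list: their median KO minus WT difference was -0.01 in number 1 and 1.12 in number 2, over 12 measured markers. The fibroblast list was higher in KO on average (adjusted p = 0.00656; adjusted p = 0.588 with an estimated correlation), and 4 members passed with the block when adjusted over the list alone: Lum (0.74), Dcn (0.67), Dpt (0.80) and Twist2 (0.82). Extracellular matrix genes moved with these markers. Their median difference over 30 genes was -0.02 in number 1 and 0.76 in number 2 (averaged list, adjusted p = 0.00263; adjusted p = 0.653 with an estimated correlation), with 0 members past either adjustment with the block. Without a block these calls ended when any of 4 arrays was left out (the KO arrays of number 1 and the WT arrays of number 2). Each such omission leaves the numbers unequal between the genotypes, so part of the difference between the numbers enters the comparison. The gene list SASP factors, KO vs WT averaged over treatments, then gave 0.176 to 0.561 and the gene list fibroblast, KO vs WT averaged over treatments, 0.342 to 0.634. For the gene list extracellular matrix, KO vs WT averaged over treatments, the direction turned without either WT array of number 2 (adjusted p = 0.864 and 0.860). Col6a2 and Col6a3, chains of collagen VI, were 0.79 and 0.89 higher on average without passing.

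The p53 target list was higher in KO (21 of 24 positive, median 0.10, adjusted p = 5.77e-04; adjusted p = 0.416 with an estimated correlation), with 0 members past the test over all genes. With the replicate number as a block 4 members passed when adjusted over the list alone: Perp (0.42), Sesn2 (0.31), Plk2 (0.30) and Trp53inp1 (0.23). Lysosomal genes (23 of 32 positive, adjusted p = 0.0152; 0.510 with an estimated correlation), immediate early genes (15 of 23 positive, adjusted p = 0.0415; 0.462 with an estimated correlation) and Schwann cell markers (8 of 9 positive, adjusted p = 0.0341; 0.462 with an estimated correlation) were also higher. With 1 value per culture and no block, camera at the preset correlation kept the lysosome call (adjusted p = 0.0383). It lost those of immediate early genes (0.0757) and Schwann cell markers (0.0598), which passed there with the replicate number as a block (0.0108 and 0.00217). Without a block, leaving out 1 array ended each call of these lists for at least 4 of the 8 arrays. The numbers are unequal between the genotypes in these fits too. The adjusted p then reached 0.449 (gene list lysosome, KO vs WT averaged over treatments), 0.453 (gene list immediate early genes, KO vs WT averaged over treatments) and 0.409 (gene list Schwann cell, KO vs WT averaged over treatments). Cholesterol synthesis genes were lower (17 of 18 negative, median -0.21, adjusted p = 0.0152; 0.653 with an estimated correlation). Their medians after sham and after UVA were -0.0008 and -0.06 in number 1 and -0.46 and -0.32 in number 2, where the fibroblast median was 1.12. For the gene list cholesterol synthesis, KO vs WT averaged over treatments, the direction turned without the WT sham array of number 2 (adjusted p = 0.863). The blocked fit called 3 further lists. Proliferation genes were lower in KO (37 of 38 negative, median -0.36, adjusted p = 2.33e-16; 0.360 with an estimated correlation; 0.0695 without the block). Their median was -0.07 in number 1 and -0.56 in number 2, against -0.01 and 1.12 for the fibroblast markers. Of these proliferation genes, 14 passed when adjusted over the list alone, among them the mitotic genes Cdc20 (-0.51), Ccna2 (-0.47) and Cenpa (-0.40). Pigmentation genes were lower (19 of 23 negative, median -0.14, adjusted p = 9.81e-05; 0.475 with an estimated correlation; 0.183 without the block), with 0 members past either adjustment. Mc1r, the melanocortin receptor, read -0.54 and Mitf, the master regulator of melanocytes, -0.27. Endothelial markers were higher (7 of 10 positive, adjusted p = 0.0190; 0.276 with an estimated correlation; 0.164 without the block). The pigmentation median was 0.05 in number 1 and -0.34 in number 2, opposite to the fibroblast markers in number 2.

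Cell cycle inhibitors and genes of lipid mediators, which bear on the study's question, did not pass as lists. The 7 CDK inhibitor genes gave an adjusted p of 0.164. Cdkn2a, which encodes p16, differed by 0.36 log2 units (0.10 in number 1 and 0.62 in number 2), Cdkn2b by 0.27 and Cdkn1a, which encodes p21, by 0.06, none of them past the test (adjusted p = 0.517, 0.505 and 0.762 with the replicate number as a block). The 30 genes of lipid mediators and lipid peroxidation had a median difference of 0.00 and an adjusted p of 0.318. Ptgs2, the inducible cyclooxygenase, differed by -0.04 in number 1 and by 1.61 in number 2, and Ptges, a prostaglandin E synthase, by 0.16 and 1.22. The remaining lists gave adjusted p values of 0.0674 (autophagy machinery), 0.863 (ATF4 and ER stress), 0.195 (heat shock), 0.495 (interferon response), 0.0695 (keratinocyte), 0.543 (myeloid cell), 0.191 (mast cell) and 0.959 (skeletal muscle). Within the interferon list the direction depended on the number, with a median KO minus WT difference of 0.21 after sham and 0.34 after UVA in number 1, and of -0.29 and -0.17 in number 2. Ifit1 was higher in KO in both (1.48 and 0.66).

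Separately after sham and after UVA, the genotype difference was of similar size for the leading genes. Nqo1 was 2.43-fold higher in KO after sham and 1.99-fold after UVA, Adh7 3.04-fold and 2.59-fold, Ap1s2 2.22-fold and 2.14-fold, Cxcl10 2.65-fold and 3.56-fold, and Moxd1 was at 0.556 and 0.519 of the WT level. None passed in either comparison: limma called 0 genes after sham and 0 after UVA, without a block (446 and 352 at an unadjusted p under 0.05) and with the replicate number as a block (1230 and 927; smallest adjusted p 0.0796 and 0.108). NRF2 targets were higher after sham (25 of 27 positive, adjusted p = 6.28e-07; 0.0743 with an estimated correlation) and after UVA (25 of 27, adjusted p = 3.71e-05; 0.127 with an estimated correlation). SASP factors were higher after sham (45 of 53 positive, adjusted p = 0.00828; 0.854 with an estimated correlation) and after UVA (43 of 53, adjusted p = 0.0217; 0.735 with an estimated correlation). Also higher after sham were p53 targets (adjusted p = 1.61e-04; 0.333 with an estimated correlation) and extracellular matrix genes (0.0454; 0.857 with an estimated correlation), while cholesterol synthesis genes were lower (0.0454; 0.854 with an estimated correlation). After UVA, extracellular matrix genes (0.0241; 0.756 with an estimated correlation), fibroblast markers (0.0371; 0.735 with an estimated correlation) and immediate early genes (0.0491; 0.728 with an estimated correlation) were higher. After sham the blocked fit called 6 further lists: proliferation (5.97e-16) and pigmentation (6.82e-07) lower, and lysosome (0.00476), fibroblast (3.71e-06), endothelial (0.0296) and Schwann cell (0.00476) higher. After UVA that block added proliferation (1.88e-09) and cholesterol synthesis (2.11e-04) as lower, and lysosome (0.0444), p53 targets (0.0248), interferon response (0.00705; median 0.34 in number 1 and -0.17 in number 2) and Schwann cell (0.01005) as higher. With an estimated correlation none of these held (adjusted p from 0.355 to 0.369 after sham and from 0.366 to 0.638 after UVA). Without a block these calls changed when 1 array was left out. Its group then holds a single replicate number, so part of the difference between the numbers enters the comparison. After sham, SASP factors gave an adjusted p of 0.883 without the KO array of number 1, and turned direction without the WT array of number 2 (0.231). The gene list extracellular matrix, KO vs WT after sham, turned without either array (0.823 and 0.0123), and the gene list cholesterol synthesis, KO vs WT after sham, without the latter (0.0556). After UVA, leaving out the KO array of number 1 or the WT array of number 2 turned the gene list SASP factors, KO vs WT after UVA (0.822 and 0.126), and the gene list extracellular matrix, KO vs WT after UVA (0.983 and 0.0126). The gene list fibroblast, KO vs WT after UVA, gave 0.925 without the former and turned without the latter (0.209). Across genes, which are not independent replicates, the genotype difference after sham correlated with that after UVA at r = 0.56 (Spearman rho 0.38), and at -0.144 without the WT UVA array of number 2. The sham and UVA arrays share cultures, so some agreement would arise without a genotype effect. Between the separate cultures of number 1 and number 2, the averaged genotype difference correlated at r = 0.06 (Spearman rho -0.01).

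The comparison of UVA with sham, averaged over genotypes, asks which genes respond to 20 J/cm² UVA-1 within 6 h. Heat shock and antioxidant genes rose. Hspa1b and Hspa1a, which encode inducible HSP70, rose 3.11-fold and 2.59-fold (log2 changes 1.64 and 1.38, SE 0.07 and 0.06, adjusted p = 7.01e-05 for each with the culture as a block), with all 4 UVA arrays above all 4 sham arrays. Slc7a11, the cystine importer that feeds glutathione synthesis, rose 2.64-fold (adjusted p = 0.00788) and Slc40a1, the iron exporter ferroportin, 1.97-fold (0.0222). The stress transcription factor gene Atf3 rose 1.67-fold (0.0233), Ddit4l 1.58-fold (0.0222), and Procr, the protein C receptor, 1.54-fold (0.00383). Gclm rose 1.46-fold (0.00150), Hspb8 1.41-fold (0.00700), Gclc 1.41-fold (0.00649) and Sqstm1 1.17-fold (0.0233). Cavin2, a coat protein of caveolae, fell by 0.47 log2 units (0.0447). Other genes that fell, with sham and UVA arrays overlapping across cultures, were Slitrk6, a neuronal membrane protein (-1.06, adjusted p = 0.0197), the peptide hormone gene Apln (-0.61, 0.0222), Ankrd1 (-0.59, 0.00727), Ngfr (-0.52, 0.0222) and the monocyte chemokine gene Ccl2 (-0.43, 0.00727). With the culture as a block 97 genes passed (53 up and 44 down). The replicate number as a block gave 3, Hspa1b, Hspa1a and Gclm (adjusted p = 0.00302, 0.00848 and 0.0338), and without a block limma called 0 (401 at an unadjusted p under 0.05). At that unadjusted level limma had 1451 genes with the replicate number as a block and 2797 with the culture as a block. The count of 97 moved widely with the setting. It was 0 when any single array was left out or when all probe sets were tested, 2 with a variance prior without a trend and 528 without the dimmest genes (0.333 of all). Centring the arrays on their medians gave 128 up and 145 down. A fit without 1 array keeps fewer than the 2 residual degrees of freedom of this fit and leaves the partner array unpaired, so it has little power.

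Of 27 NRF2 targets, 24 had a positive UVA minus sham difference (median 0.31). The list was called without a block (adjusted p = 1.87e-11; 0.0287 with an estimated correlation) and with the culture as a block (2.55e-24; 0.108 with an estimated correlation). In that fit 13 members rose over all genes and 19 when adjusted over the list alone. They include Nqo1 (1.53-fold), Gsr, the glutathione reductase (1.43-fold), Taldo1 (1.39-fold), Txnrd1, the thioredoxin reductase (1.36-fold) and Hmox1, the inducible heme oxygenase (1.36-fold). All 14 heat shock genes had a positive difference (adjusted p = 6.88e-09; 0.0304 with an estimated correlation). The culture fit had 3 rising over all genes and 9 when adjusted over the list alone. Hsph1 (0.36 log2 units, adjusted p = 0.0618) passed only the latter. Of 24 p53 targets, 22 were positive (adjusted p = 3.21e-07; 0.104 with an estimated correlation). With the culture as a block Trp53inp1 rose 1.49-fold over all genes, and 12 members rose when adjusted over the list alone, among them Cdkn1a (0.27) and Mdm2 (0.22). Autophagy genes were higher (30 of 39 positive, median 0.09, adjusted p = 1.46e-04; 0.146 with an estimated correlation). Sqstm1 passed over all genes, and 8 rose and 1 fell when adjusted over the list alone, Gabarapl1 (0.22) and Tfe3 (0.20) among those that rose. The ATF4 and ER stress list was higher (12 of 23 positive, adjusted p = 0.00710; 0.883 with an estimated correlation). Its members that rose over all genes were 3, Slc7a11, Atf3 and Ppp1r15a (0.43), of which Slc7a11 also counts among the NRF2 targets. Cholesterol synthesis genes were lower (16 of 18 negative, median -0.14, adjusted p = 0.0145; 0.944 with an estimated correlation). With the culture as a block Hmgcs1 (-0.33) and Mvd (-0.39) fell over all genes and 9 fell when adjusted over the list alone. The gene list cholesterol synthesis, UVA vs sham averaged over genotypes, turned direction in the fit without a block when the WT sham array of number 2 was left out (adjusted p = 0.608). The gene list ATF4 and ER stress, UVA vs sham averaged over genotypes, lost its call without any of 4 arrays (0.147 to 0.739).

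Several lists were called with the culture as a block and not without a block, and each lost that call with an estimated correlation. SASP factors were lower after UVA (18 of 53 positive, adjusted p = 9.75e-04; 0.271 with an estimated correlation; 0.389 without a block). Ccl2 passed over all genes, and 4 rose and 10 fell when adjusted over the list alone, with changes of -0.26 for Timp1 and 0.25 for Mmp10. Extracellular matrix genes were lower (0 of 30 positive, adjusted p = 6.26e-13; 0.108 with an estimated correlation; 0.128 without a block). Lama2 (-0.41) fell over all genes, and 13 members fell when adjusted over the list alone. Fibroblast markers were lower as well (1 of 12 positive, median -0.10, adjusted p = 5.45e-05; 0.271 with an estimated correlation; 0.627 without a block), Pdgfrb (-0.28) falling over all genes. Proliferation genes were lower (adjusted p = 1.71e-06, 0.446 with an estimated correlation, 0.294 without a block). Their median change was -0.02 in WT and -0.03 in KO of number 1, and -0.26 and -0.09 in number 2. Interferon response genes (3.60e-05, 0.358 with an estimated correlation, 0.128 without a block) and Schwann cell markers (0.0414, 0.358 with an estimated correlation, 0.294 without a block) were lower. Immediate early genes were higher (0.00108; 0.271 with an estimated correlation; 0.0605 without a block), Fosb rising by 0.76. For the pigmentation list (adjusted p = 0.911 without a block), Ednrb, the endothelin B receptor, rose by 0.50 and Mc1r fell by 0.30 with the culture as a block (adjusted p = 0.0347 for each). Plin2, a lipid droplet protein, rose by 0.31 (adjusted p = 0.04998) in the lipid list, which did not pass (0.867 without a block). The other lists gave, without a block, adjusted p values of 0.498 (CDK inhibitors), 0.911 (lysosome), 0.733 (keratinocyte), 0.911 (myeloid cell), 0.819 (mast cell), 0.819 (endothelial cell) and 0.216 (skeletal muscle).

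**Figure D2:**
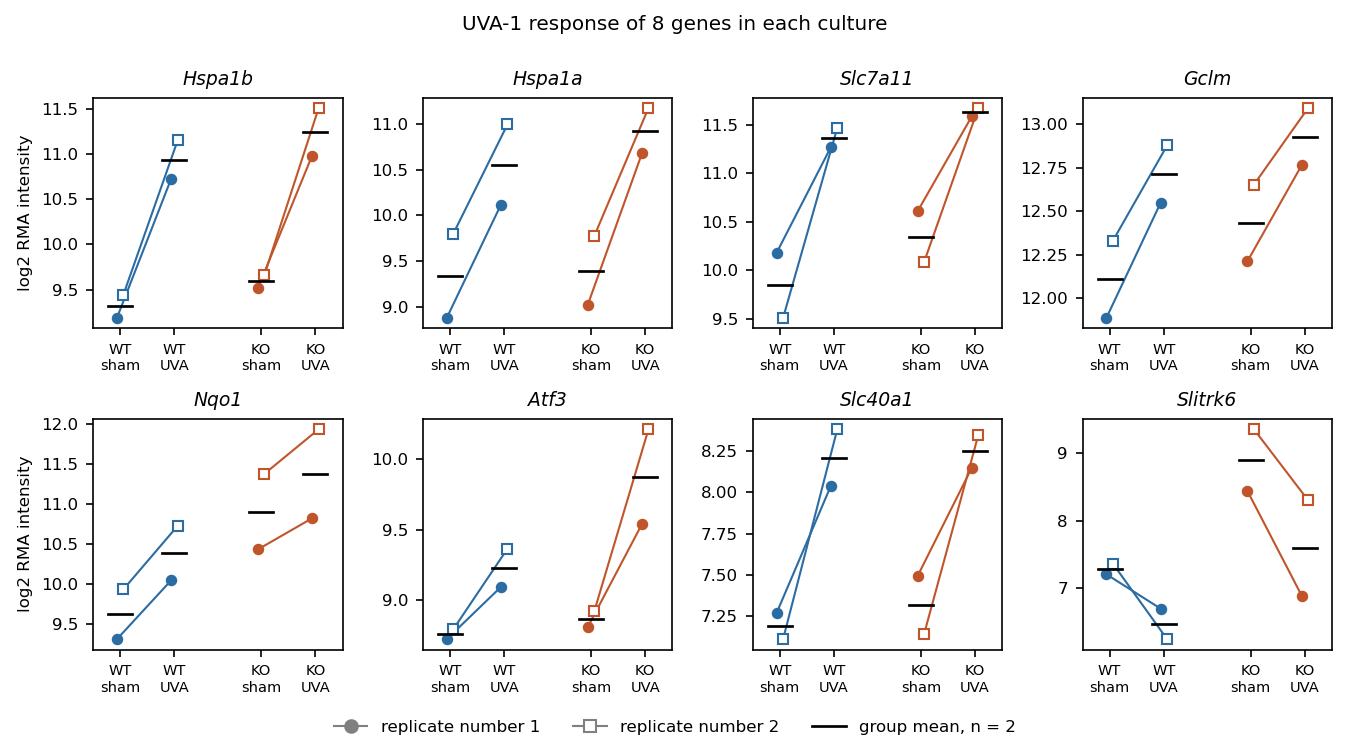
Log2 RMA intensity of 8 genes in the sham and UVA array of each culture (WT in blue, KO in orange, filled circles number 1, open squares number 2, black bars group means of 2). Hspa1b rose by 1.54 and 1.70 log2 units in the WT cultures of number 1 and 2 and by 1.47 and 1.84 in the KO cultures.

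In WT cells alone, UVA raised Hspa1b 3.08-fold, Hspa1a 2.33-fold, Nqo1 1.70-fold (adjusted p = 0.0130 with the culture as a block), Procr 1.60-fold, Trp53inp1 1.56-fold, Gclm 1.52-fold (adjusted p = 0.0110), Hspb8 1.5-fold and Taldo1 1.46-fold. In that fit 12 genes passed, all higher. After a second quantile normalization 22 passed (17 up and 5 down), and after centring 25 (20 up and 5 down). The replicate number as a block gave 1, Hspa1b (adjusted p = 0.0343), and the fit without a block 0 (342 at an unadjusted p under 0.05, limma). Adh7 (1.68-fold) and Hmox1 (1.40-fold) were also among the 12, with arrays that overlapped. Slc7a11 was 2.87-fold higher without passing (adjusted p = 0.0618). Without a block 4 lists were higher: NRF2 targets (26 of 27 positive, adjusted p = 3.42e-09; 0.0437 with an estimated correlation), p53 targets (23 of 24, 3.87e-07; 0.102 with an estimated correlation), heat shock (13 of 14, 1.05e-05; 0.0754 with an estimated correlation) and autophagy machinery (29 of 39, 0.00241; 0.250 with an estimated correlation). Lower lists were interferon response (22 of 23 negative, 0.0106; 0.875 with an estimated correlation) and cholesterol synthesis (16 of 18 negative, 0.0274; 0.875 with an estimated correlation). Both turned direction without the UVA array of number 1 or the sham array of number 2, to an adjusted p of 0.297 and 0.0184 for the gene list interferon response, UVA vs sham in WT, and of 0.597 and 0.0339 for the gene list cholesterol synthesis, UVA vs sham in WT. The replicate number as a block added proliferation (1.59e-06), pigmentation (0.0433) and extracellular matrix (0.0181) as lower, and the culture as a block added SASP factors (0.0115) and fibroblast markers (3.03e-04) as lower and immediate early genes (0.0282) as higher. None of these 6 held with an estimated correlation (adjusted p from 0.139 to 0.757).

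In KO cells alone, UVA raised Hspa1b 3.15-fold and Hspa1a 2.89-fold (adjusted p = 0.00107 and 9.33e-04 with the culture as a block, 0.0298 and 0.0426 with the replicate number as a block). These were the 2 genes that passed with either block. With the culture as a block, 7 passed after a second quantile normalization (6 up and 1 down) and 14 after centring (10 up and 4 down). Without a block limma called 0 (348 at an unadjusted p under 0.05). Slc7a11 was 2.43-fold higher, Atf3 2.02-fold and Gclc 1.40-fold, and Slitrk6 was at 0.406 of the sham level, without passing (adjusted p = 0.163, 0.117, 0.117 and 0.117 with the culture as a block). NRF2 targets (25 of 27 positive, adjusted p = 7.25e-07; 0.0477 with an estimated correlation) and heat shock genes (13 of 14, 7.25e-07; 0.0477 with an estimated correlation) were higher as lists, as were p53 targets (18 of 24, 0.0119; 0.468 with an estimated correlation), autophagy machinery (29 of 39, 0.0101; 0.467 with an estimated correlation) and ATF4 and ER stress (16 of 23, 0.00453; 0.823 with an estimated correlation). The gene list ATF4 and ER stress, UVA vs sham in KO, turned direction without the sham array of number 2 (0.944). Leaving out 1 array also ended the calls of the gene list autophagy machinery, UVA vs sham in KO (0.295 and 0.297 without the sham or UVA array of number 2), and the gene list p53 targets, UVA vs sham in KO (0.0697 and 0.403 without these, and 0.114 without the sham array of number 1). The replicate number as a block added immediate early genes (0.00666) as higher and cholesterol synthesis (0.00115) and extracellular matrix (0.00666) as lower, and the culture as a block added pigmentation (0.00265) as higher and SASP factors (0.00137), fibroblast markers (0.00197), proliferation (0.0483) and Schwann cell markers (0.0483) as lower. None of these 8 held with an estimated correlation (adjusted p from 0.146 to 0.879).

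Whether the response to UVA-1 differed between the genotypes was tested by the interaction, the UVA change in KO minus that in WT. No gene passed with limma: 0 without a block (294 at an unadjusted p under 0.05), 0 with the replicate number as a block (458) and 0 with the culture as a block (766). Nqo1 was 0.47 higher after UVA in KO and 0.76 higher in WT, a difference of -0.29 (SE 0.10 with the culture as a block, adjusted p = 1). Atf3 was 1.01 higher in KO and 0.47 higher in WT, a difference of 0.54 (SE 0.18, adjusted p = 1). The differences for Sqstm1 and Atg7 were -0.06 and -0.01. No list passed without a block. The replicate number as a block gave 4 lists: pigmentation (adjusted p = 0.00193) and interferon response (0.00193), with 21 of 23 members more positive in KO in each, proliferation (0.0479), with 28 of 38, and p53 targets (0.0349), with 3 of 24. Each lost the call with an estimated correlation (adjusted p = 0.943). Across genes the UVA change in WT correlated with that in KO at r = 0.30 (Spearman rho 0.26). The correlation across genes of the UVA effect in WT and in KO was 0.0572 without the WT sham array of number 1 and at most 0.237 with any 1 array left out. The averaged UVA change correlated with the averaged genotype difference at -0.06.

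**Figure D3:**
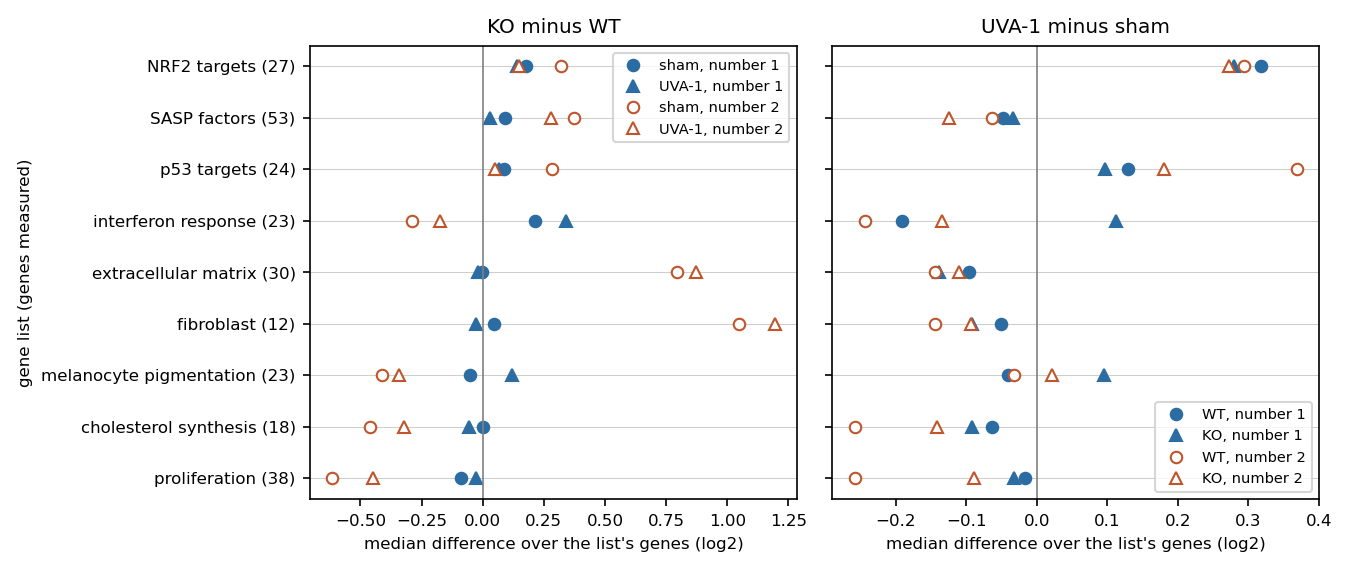
Median difference over the measured genes of 9 lists (number of genes in parentheses), KO minus WT on the left and UVA-1 minus sham on the right, each computed within 1 replicate number. After UVA, NRF2 targets lie between 0.27 and 0.32 in all 4 cultures, while the fibroblast and extracellular matrix medians between genotypes lie near 0 in number 1 and between 0.80 and 1.194 in number 2.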

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

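All 5 results here come from the fit with each combination of genotype and number as a block, which was chosen after the data were seen, and so were all tests but the counts of splits without a block. In that fit the UVA response of 5 gene lists differed between the genotypes by the interaction test. Pigmentation genes (21 of 23 more positive in KO, median 0.11, adjusted p = 1.88e-07) and interferon response genes (21 of 23, median 0.20, adjusted p = 5.32e-07) were higher after UVA in KO than the WT response would give. Proliferation genes were also more positive in KO (28 of 38, median 0.09, adjusted p = 0.00128). NRF2 targets (7 of 27 more positive, median -0.06, adjusted p = 0.0154) and p53 targets (3 of 24, median -0.11, adjusted p = 0.00428) responded less in KO. None held with an estimated correlation (adjusted p = 0.881 each), and none was called without a block. The proliferation and p53 results lost their direction without the WT sham or the WT UVA array of number 2. Within numbers, the median UVA change of the interferon list was -0.19 in WT and 0.11 in KO of number 1, and -0.24 and -0.14 in number 2. No single gene passed the interaction test.

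The counts of called genes were set against other splits of the 8 arrays. Without a block the real genotype split called 0 genes and so did most others. All 35 splits gave a count at least as large, which a real count of 0 fixes in advance, so this share tests nothing. The highest count was 7065 genes, for the split by replicate number. For UVA against sham the real count was also 0, and the 35 of 35 was fixed in the same way, with 7227 genes for the split by number. Splits that call so many genes point to a structure of the samples, the replicate number. The next fit had number and treatment as covariates and no interaction term, unlike the blocked fit that called 7 genes. In it the real genotype split called 17 genes (1 of 34 splits as large, highest other 2). Nearly all of these splits part the arrays of a culture, which correlate at r = 0.996 to 0.997. Only 2 of them keep cultures whole, the real one and 1 that called 0 genes, too few for a share under 0.05. With 1 value per culture limma called 0 genes (257 at an unadjusted p under 0.05; 736 with the replicate number as a block). For UVA against sham within cultures, only 8 exchanges exist, too few for a share under 0.05; the real one called 97 genes and the highest other 0.

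The higher SASP and NRF2 lists in KO were weighed against a larger share of fibroblast RNA in the KO arrays. Fibroblast markers differed between genotypes in number 2 (median 1.12, 95% interval 0.87 to 1.32) and had a median near 0 in number 1 (-0.01, -0.06 to 0.18). Number 1 was therefore used for the comparison, although the upper end of that interval leaves room for a small fibroblast difference. Each number holds 1 culture per genotype, and those of number 1 are not matched in Y-linked signal (Eif2s3y, Kdm5d and Uty 2.50, 1.93 and 2.31 higher in KO). The NRF2 median in number 1 was 0.160 (0.0943 to 0.254), against 0.240 in number 2, where the fibroblast median was 1.12. Within these cultures this argues against fibroblast content as the whole cause for that list. A comparison of single cultures cannot test it for the genotype. Schwann cell markers, some of which melanocytes express, were also higher in KO in number 1 (median 0.229, 0.00199 to 0.930; Ngfr read 7.89 in WT and 9.08 in KO), and whether RNA of such cells adds to the NRF2 difference was not tested. The KO genotype remains a hypothesis, with a difference between the pups (sex included) or cultures untested. The SASP median in number 1 was 0.0296 (-0.0143 to 0.112) against 0.312 in number 2. More fibroblast RNA in the KO than in the WT culture of number 2 would give such a gap. Part of the SASP difference in number 2 may therefore come from fibroblasts. Mmp13, Ccl5 and Cxcl10, the members with the smallest p, differed by 0.88, 0.94 and 1.73 in number 1. Ccl5 and Cxcl10, which interferons induce, differed by 1.47 and 1.51 in number 2. The interferon list had medians of 0.21 after sham and 0.34 after UVA in number 1, and of -0.29 and -0.17 in number 2.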

How the results depend on the processing

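The culture as a block, the arrays of 1 number alone, 1 value per culture and every alternative run inside a blocked fit were chosen after the data were seen. The other settings were chosen beforehand. With 1 array left out, the lone array of a group is assumed to vary like the other groups. Without a block that group then holds a single replicate number, so part of the difference between the numbers enters its comparisons. Such fits also keep fewer residual degrees of freedom. Other reasons why values moved were not tested. Rounded intensities limit what dim genes can show. Without a block limma called 0 genes in all 7 comparisons under every setting chosen beforehand (294 to 517 at an unadjusted p under 0.05 as reported). The replicate block gave 7 genes for KO against WT averaged, 3 for UVA averaged, 1 for UVA in WT and 2 in KO, and changed no other gene count. The culture as a block gave 97, 12 and 2 for UVA averaged, in WT and in KO. For genes changed, KO vs WT averaged over treatments, the arrays of number 2 alone gave 721. A fit to 1 number sets 1 KO culture against 1 WT culture, with their sham and UVA arrays as replicates, so this count and the p-values from number 1 alone do not test the genotype. The 7 genotype calls with the replicate block became 5 to 10 under the other settings, and 2 of them were shared with the 5 called when all probe sets were tested. With 1 value per culture there were 0 without the block and 0 with it. The counts of 97, 12 and 2 became 2, 0 and 0 without a trend, 382, 39 and 24 with a robust prior, and 528, 97 and 44 without the dimmest genes, where fewer genes were tested. They were 235, 22 and 7 after quantile normalization, 273, 25 and 14 after centring, and 0, 0 and 0 with all probe sets. Leaving out any 1 array left 0 of the 7, 97, 12 and 2.

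The correlation across genes of the KO effect after sham and after UVA was 0.721 without the dimmest genes and -0.144 to 0.579 with 1 array left out, and it was also negative without the WT sham array of number 2 (-0.0517). The correlation across genes of the UVA effect in WT and in KO was 0.475 and 0.0572 to 0.237. Among 169 gene comparisons only Atg7 turned sign in the fits reported, always with a change near 0. With 1 array left out, the log2 fold change of Atg7, UVA vs sham in WT, ran from -0.0461 to 0.0217. The log2 fold change of Atg7, UVA vs sham in KO, ran from -0.0476 to 0.00962, and the log2 fold change of Atg7, UVA vs sham averaged over genotypes, from -0.0325 to 0.00135. The log2 fold change of Atg7, interaction of genotype and UVA, ran from -0.0407 to 0.0271 (0.0218 without a KO array of number 1) and was 0.00693 after centring. In the fit without a block 34 of the 169 turned sign with 1 array left out.

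The lists that turned direction with 1 array left out had these ranges of adjusted p, with the value at the turn in brackets. The gene list SASP factors, KO vs WT after sham, ran from 9.73e-08 to 0.883 (0.231), the gene list cholesterol synthesis, KO vs WT after sham, from 2.80e-07 to 0.934 (0.0556), and the gene list extracellular matrix, KO vs WT after sham, from 5.12e-08 to 0.823 (0.0123 and 0.823). The gene list SASP factors, KO vs WT after UVA, ran from 1.80e-07 to 0.822 (0.126 and 0.822), the gene list extracellular matrix, KO vs WT after UVA, from 1.42e-09 to 0.983 (0.0126 and 0.983), and the gene list fibroblast, KO vs WT after UVA, from 3.07e-06 to 0.925 (0.209). The gene list cholesterol synthesis, KO vs WT averaged over treatments, ran from 8.07e-07 to 0.863 (0.863), and the gene list extracellular matrix, KO vs WT averaged over treatments, from 7.87e-09 to 0.864 (0.860 and 0.864), turning also in number 1 alone (0.673). The gene list interferon response, UVA vs sham in WT, ran from 3.29e-10 to 0.297 (0.0184 and 0.297), and the gene list cholesterol synthesis, UVA vs sham in WT, from 2.39e-08 to 0.597 (0.0339 and 0.597). The gene list ATF4 and ER stress, UVA vs sham in KO, ran from 1.46e-05 to 0.944 (0.944), and the gene list cholesterol synthesis, UVA vs sham averaged over genotypes, from 1.23e-07 to 0.807 (0.608). Pigmentation in KO against WT averaged, with the replicate number as a block, turned in number 1 alone (0.234). The gene list proliferation with the culture as a block, interaction of genotype and UVA, ran from 3.28e-08 to 0.904, and the gene list p53 targets with the culture as a block, interaction of genotype and UVA, from 9.54e-07 to 0.904 (each 0.902 and 0.904). All 36 list calls made without a block held with the replicate block and without the dimmest genes. With an estimated correlation 6 of them held and 30 were lost. Of all 57 list calls, 2 held and 55 were lost with the replicate block and an estimated correlation.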

Other observations

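The tests here were chosen after the data were seen. The cultures of number 1 and number 2 differed far more than the genotypes or treatments. In WT, number 2 had higher proliferation genes (median over 38 genes 2.23 log2 units, 95% interval 1.77 to 2.69), pigmentation genes (1.28) and interferon response genes (1.00), and lower fibroblast markers (-2.15) and SASP factors (-1.08). In KO the same shifts were 1.75, 0.88, 0.33, -1.14 and -0.74. Mki67, a marker of cycling cells, read 7.74 in the WT culture of number 1 and 11.4 in that of number 2 (log2, mean of the sham and UVA arrays), and Top2a, a mitotic topoisomerase, 6.95 and 10.5. Tyr, the tyrosinase that starts melanin synthesis, read 10.4 and 12.1, while Tyrp1, Dct and Pmel, abundant in melanocytes, read 13.4 to 14.2 in every culture. Col1a1, a collagen I chain, read 12.8 and 9.83 in WT and 12.7 and 11.03 in KO, and Dcn, the proteoglycan decorin, 13.0 and 11.01 in WT and 13.1 and 12.2 in KO. NRF2 targets moved both ways between numbers, with medians of -0.07 (-0.53 to 0.25) in WT and -0.02 (-0.22 to 0.33) in KO.

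A share of fibroblasts that differs between the numbers, and nothing else, would dilute proliferation and pigmentation genes alike. Proliferation genes exceeded pigmentation genes in their rise from number 1 to number 2 by 0.953 in WT and by 0.872 (0.378 to 1.33) in KO. Over the 14 pigmentation genes that read no higher than the highest proliferation gene, away from the array ceiling, the excess was 0.949 (0.226 to 1.40) in WT and 0.627 (0.3005 to 1.16) in KO. This argues against such dilution as the whole cause but cannot exclude it. The intervals treat genes as independent, and whether fibroblasts express some of the pigmentation genes was not tested. A single array batch effect per number would shift fibroblast markers alike in both genotypes, but the shift differed between them by 1.01 (0.432 to 1.25). A lower fibroblast share together with faster division in the number 2 cultures remains a hypothesis, and a batch effect added to it cannot be ruled out, since the labels give no batch.

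All samples are labelled female, and Xist, which silences the second X chromosome, read 11.8 to 12.4 in all 8 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read 6.22, 5.30 and 5.06 in the WT culture of number 1 and 9.68, 8.34 and 8.55 in that of number 2; the KO cultures read 8.72, 7.23 and 7.37 in number 1 and 9.45, 8.15 and 8.37 in number 2. Cross-hybridisation from the X-linked homologs is excluded as the whole cause, since Kdm5c and Kdm6a differed between the WT cultures by at most 0.297, and Eif2s3x by 0.05 and -0.13 in the 2 probe sets that it shares with Gm2223. The smallest difference of a Y-linked gene between these cultures was 3.04, with Xist within 0.585 over all arrays, a pattern consistent with cultures that pooled male and female pups in different shares. A wrong sex label for a culture of a single male does not go with the Xist level.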
